A study of Mus musculus with 6 samples.

How the data were processed

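Tibialis anterior, a fast muscle of the lower hindlimb, was taken from male C57Bl/6 mice aged 18 weeks. Per the labels' protocols, food was withdrawn at 1800 hr, and at about 0800 hr the mice were assigned at random to go on fasting or to eat for 30 minutes. Food was then withheld from both groups for 4 hr before the muscle was removed. RNA came from pieces of about 25 mg, and 300 ng of it per sample was labelled with biotin by a whole-transcript method for hybridisation to arrays. The labels name 3 fasted samples, with replicate numbers 1, 3 and 5, and 3 refed samples, with numbers 7, 9 and 11. The groups share no replicate number, so no pairing was fitted. The labels do not state that each array came from a mouse of its own, and p-values measure the spread between these 6 arrays.

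The authors deposited 1 table of processed values on the log2 scale, with 41345 array features and 6 columns, all of them used. Its scale was settled from the values: for all 470 entries of the authors' list, the difference of the group means equalled log2 of the authors' ratio within 1.81e-05. The submitters' processing notes name Partek, with no version or role. Background correction, summarisation to features, normalization between arrays and the genome build are not given in the sources used here. The column medians lay between 5.02 and 5.06. The table held no mark of control features, so none was left out.

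The authors also deposited a list of 470 features with, per the file headers, a linear ratio (fold) and an unadjusted p-value for refed against fasted arrays and for comparisons with further arrays, as well as F ratios and sums of squares. The deposited p-values could be recomputed within a relative difference of 4.93e-05 from a linear model over 4 groups of 3 arrays with 8 error degrees of freedom. The largest p-value in the authors' deposited list was 0.0499977 and the smallest change 1.50-fold, so the list held features with p under 0.05 and at least 1.5-fold. The list gives a gene symbol for 134 features and none for 336. It is also the only source here that pairs features with genes, so 41211 of the 41345 features are unnamed. Through the accessions in the list, 73 symbols matched a RefSeq table of assembly GRCm38.p6, which updated 3 of them (Depp1, Aopep and Pramel31). Chromosomes and bands are those of the authors' list.

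Refed and fasted arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the log2 values, no covariate, no filter on dim features), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The design fixed before the data were examined called for 1 feature per gene where a table pairs features with genes, and otherwise for all features. All features were therefore tested. The same fit was tested on simulated data, in which 200 of the 41345 features were changed in each of 10 simulations. At the adjusted threshold it called 2.6% of the 1.5-fold changes, 40.2% of the 2-fold changes, 71.4% of the 3-fold changes and 81.2% of the 4-fold changes, with 4.3 false calls per simulation. The number of arrays limits the precision: the median 95% confidence interval of a difference reached 0.37 to either side on the log2 scale. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

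Before the data were examined, 33 gene lists with 875 distinct genes were fixed, 23 of them for processes of fasting and feeding in muscle and 10 for other cell types that a piece of muscle can hold. Set tests across all members (camera and fry) were planned and were not run, because members outside the authors' list could not be matched to a feature. A pair of substitutes was chosen after the data were seen. The members in the list were adjusted over the list alone, every other member being counted as unchanged. The number of members in the authors' list was also set against that of the other fixed genes with a one-sided Fisher's exact test. The authors' list was selected on the same arrays, so neither is independent evidence.

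The genes named in the report followed a rule fixed before the data were examined. With fewer than 4 genes past the threshold, it took the 8 genes with the smallest p in each direction. Predicted, clone, microRNA and small nucleolar RNA names were left out. It added up to 2 members of each process list, 1 member of each list of another cell type, and 11 genes known from work on fasting. Because of the missing names, the rule was applied to the 134 features with a symbol and gave 23. Of the 11 known genes, Ddit4 and Trim63 have a named feature, and the other 9 (Pdk4, Fbxo32, Foxo1, Klf15, Hk2, Srebf1, Irs2, Txnip and Myc) are not analysed here. Alternatives covered normalization, filters on dim features, array weights, variance moderation, thresholds and leaving out each array in turn.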

Results

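The data are log2 signals of 41345 features on 6 arrays of mouse tibialis anterior, 3 from mice that fasted overnight and through the morning and 3 from mice that ate for 30 minutes after the night's fast and were killed 4 hr later. The comparison asks how gene expression in skeletal muscle differs after a meal. The 6 arrays were close to each other: Pearson's r between arrays across features was 0.978 to 0.982 within a group and 0.979 to 0.983 between groups, features not being independent replicates.

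In refed muscle 14 of the 23 genes named by the rule had lower values and 9 higher ones, a split partly set by the rule's 8 genes per direction. The lower ones include members of the list fixed for the glucocorticoid response. Of these, Ddit4 is also the 1 mTORC1 member in the authors' list, and Trim63 the 1 proteolysis member. Depp1 (chromosome 6, band E3), a target of the FoxO factors, was 3.85-fold lower, at 7.97 ± 0.37 against 9.91 ± 0.37 in fasted muscle (log2 signal, SD, n = 3). Ddit4 (REDD1; chromosome 10, band B3), an inhibitor of mTORC1, was 2.97-fold lower, at 6.62 ± 0.41 against 8.19 ± 0.61. Cebpd, a transcription factor, was 2.06-fold lower, and the alpha-arrestins Arrdc2 and Arrdc3 were 1.96-fold and 1.87-fold lower. Trim63 (MuRF1; chromosome 4, band D3), a ubiquitin ligase of the sarcomere, was 1.58-fold lower at one of the brightest signals on the array, 11.13 ± 0.18 against 11.79 ± 0.22. None of these differences passed the test across all features (limma, adjusted p 0.801 to 0.964 for the 23 genes named by the rule), although in each of the 23 all 3 refed values lay on one side of the 3 fasted values.

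The separation is in part a result of how these genes were chosen, by small p and from a list made on these same arrays. Over the whole table the groups did not overlap for 3950 features, or 9.55%, where chance gives 10% for 3 against 3. The limma test called 0 of 41345 features at adjusted p under 0.05, with a smallest adjusted p of 0.686. At an unadjusted p under 0.05 it found 858 features higher and 1151 lower in refed muscle, 2009 in all, where 2067.2 were due by chance. The model without moderation also called 0 at the adjusted threshold, and found 884 higher and 967 lower at the unadjusted one. The smallest unadjusted p, 1.66e-05, belonged to an unnamed feature of low signal.

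**Figure D1:**
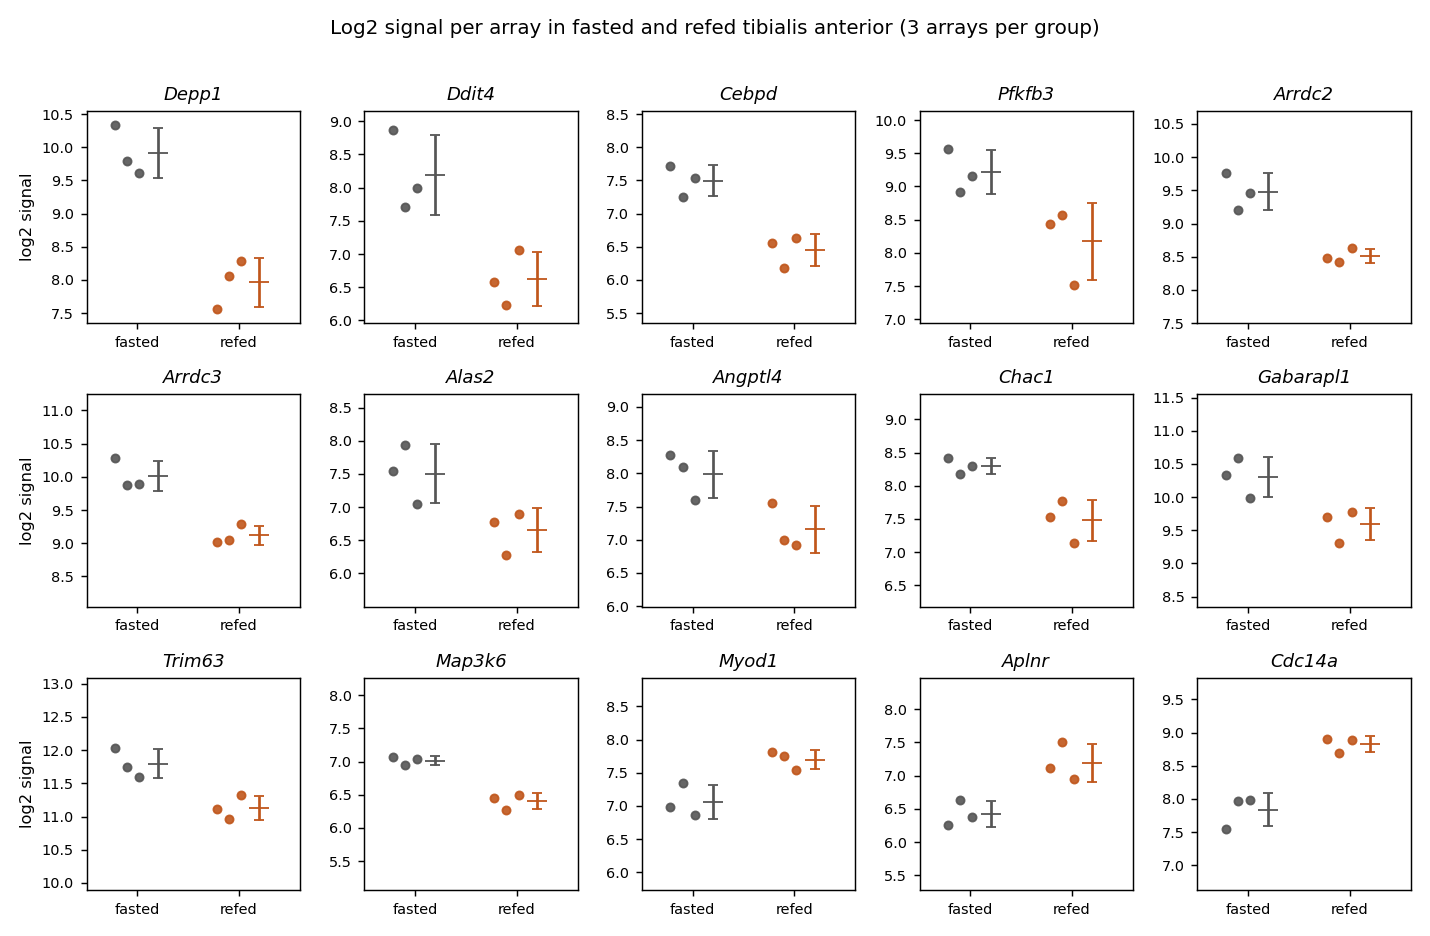
Log2 signal on each array (points) for the 15 genes named by the rule that are among the 10336 brightest features, in fasted (grey) and refed (orange) muscle; bars give mean ± SD, n = 3. In 12 genes the 3 refed values lie below the 3 fasted values and in 3 genes (Myod1, Aplnr and Cdc14a) above them, and none passed limma at adjusted p under 0.05.

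Of the fixed lists, the glucocorticoid response had the most members in the authors' deposited list. Of its 31 genes, 6 were there, and all 6 were lower in refed muscle: Ddit4, Cebpd, Arrdc2, Angptl4, Gadd45g and Trim63. Their mean was 7.97 ± 0.18 in refed and 8.97 ± 0.34 in fasted muscle (log2 signal, SD, n = 3), a difference of -0.9995; the 6 entered through a list selected on these arrays, so this separation is no test of its own. By limma, 4 of them fell when adjusted over the list alone, with members outside the authors' list counted as p = 1: Cebpd (adjusted p = 0.00952), Arrdc2 (0.00952), Ddit4 (0.0217) and Trim63 (0.0318). Angptl4, an inhibitor of lipoprotein lipase, was 1.78-fold lower (0.0590), and Gadd45g, a stress-response gene outside the naming rule that was added after its values were seen, was 1.89-fold lower (0.107). None passed over all features or over the 875 genes of all lists, where the smallest limma adjusted p was 0.269. The other 844 fixed genes had 6 in the authors' list (Fisher's exact test, one-sided, p = 9.56e-07, adjusted over 33 lists 3.15e-05). That test was chosen after the data were seen, treats genes as independent and assumes that the lists are equally well covered by named features. Under the model without moderation 0 of the 6 passed over the list alone, and Cebpd and Arrdc2 alone passed whichever array was left out. Trim63 was lost without fasted replicate 1, fasted replicate 3, refed replicate 7 or refed replicate 9, and Ddit4 without refed replicate 7 or 9.

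A pair of red blood cell transcripts was in the authors' list with lower values in refed muscle. Alas2, the erythroid enzyme of haem synthesis, was 1.81-fold lower in refed muscle, at 6.65 ± 0.33 against 7.51 ± 0.44 (SD, n = 3), and the beta globin Hbb-bt, named after its values were seen, was 1.701-fold lower. The mean of both was 6.35 ± 0.38 in refed and 7.16 ± 0.45 in fasted muscle. These were 2 of the 14 genes of the erythroid list. Neither passed the limma test over that list alone (adjusted p 0.187 and 0.236), and the list's Fisher's exact test had an adjusted p of 0.236. With the mean of these transcripts as a covariate, all 6 glucocorticoid members were still lower, with a mean difference of -0.924 (SE 0.394) against -0.9995 (SE 0.223), and 0 passed over the list alone. Alas2 and Hbb-bt also entered through the list selected on these arrays, so the covariate follows the groups in part by selection. Smaller differences and wider SEs under it are then partly built in. Single members moved apart: Trim63 went from -0.66 to -0.44 and Angptl4 from -0.84 to -0.50, while Gadd45g went from -0.92 to -1.23.

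Single members of other process lists were in the authors' deposited list too. The autophagy gene Gabarapl1, which codes for an ATG8 protein of the autophagosome, was 1.63-fold lower in refed muscle (9.59 ± 0.24 against 10.30 ± 0.30, SD, n = 3). With the red cell covariate its difference went from -0.71 (SE 0.196) to -0.17 (SE 0.174). Pfkfb3, which makes the sugar bisphosphate that activates glycolysis, was 2.06-fold lower (8.17 ± 0.58 against 9.22 ± 0.33). Its difference of -1.04 became -0.71 without refed replicate 11, the lowest of its refed arrays. Chac1, a glutathione-degrading enzyme induced by ATF4, was 1.76-fold lower. The kinase gene Map3k6, which belongs to no fixed list, was 1.53-fold lower. Myod1, the myogenic transcription factor, was the one higher of the 12 list genes in the authors' list, at 1.55-fold (7.70 ± 0.14 against 7.06 ± 0.25). Over its own list alone none of Trim63 (proteolysis, limma adjusted p = 0.131), Gabarapl1 (0.310), Angptl4 (fatty acid oxidation, 0.371), Pfkfb3 (glucose and glycogen, 0.362), Ddit4 (mTORC1, 0.0964), Chac1 (ATF4 response, 0.0692) or Myod1 (myogenic factors, 0.152) passed.

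In 24 of the 33 lists no member was in the authors' list, 15 of them process lists and 9 of other cell types. The former were fatty acid synthesis, cholesterol synthesis, insulin and IGF signalling, amino acid catabolism, ribosome biogenesis, ribosomal proteins, translation factors, endoplasmic reticulum chaperones, heat shock chaperones, the circadian clock, mitochondrial respiration, immediate early genes, the cell cycle, and the fast and slow fibre genes. The latter were adipocytes, endothelium, pericytes and smooth muscle, fibroblasts, tendon, macrophages, neutrophils, lymphocytes and Schwann cells. For these genes the data used here show only that none was named in the authors' list. Its features had an unadjusted p under 0.05 in the authors' model and a change of at least 1.5-fold. Of these features 336 carry no symbol, so a member may be among them. Smaller shifts of the 24 lists were not analysed here, since their members carry no name outside the authors' list.

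Among genes higher in refed muscle, Cdc14a, a phosphatase of the cell cycle, had the largest difference of the named features among the 10336 brightest, at 1.99-fold (8.83 ± 0.12 against 7.84 ± 0.25, log2 signal, SD, n = 3). Cish, an inhibitor of cytokine receptor signalling that STAT5 induces, was 1.77-fold higher, and Aplnr, the apelin receptor, was 1.696-fold higher. The other features that the rule named were of low signal. Mug-ps1, Olfr429, Gpr149, Vmn2r33 and Hsfy2 were 1.72-fold, 1.66-fold, 1.58-fold, 1.57-fold and 1.51-fold higher, and Igkv4-56 and C1s2 were 1.58-fold and 1.54-fold lower.

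The authors' deposited list, made without correction for multiple tests, held 160 features higher and 310 lower in refed muscle. Of its 134 named features, 50 were higher and 84 lower; 71 had predicted, clone or microRNA names, and 18 were olfactory or vomeronasal receptors. Its named features were dim, with a median level of 3.39 against 5.03 for all features on the log2 scale. The limma sign was the same for all 470, as it must be on the same arrays; 457 had an unadjusted limma p under 0.05 and 0 an adjusted p under 0.05. With the fold threshold added, limma found 247 features higher and 480 lower, of which 270 were not in the authors' list.

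**Figure D2:**
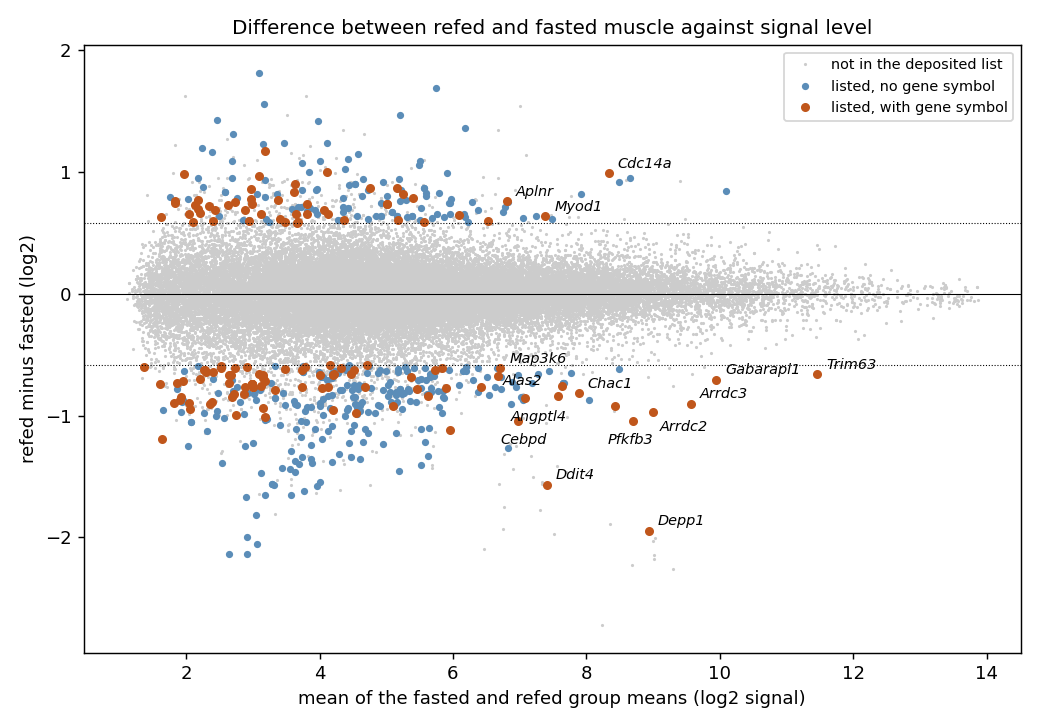
Refed minus fasted log2 signal against the mean log2 signal for all 41345 features; grey points are outside the authors' deposited list, blue points are listed without a gene symbol, and orange points are the 134 listed with one, dotted lines mark 1.5-fold, and the labelled genes are those of the rule among the 10336 brightest features. Of the 470 listed features 51 lie above a log2 signal of 6.46, and Depp1 is the lowest of the labelled genes at -1.95.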

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

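The authors' deposited table holds a comparison that the report does not use, of arrays numbered 8, 10 and 12 with arrays numbered 2, 4 and 6. No label used here gives these arrays a group or says whether they came from the same mice. Of the 470 listed features, 75 had an unadjusted p under 0.05 in that comparison as well. Both p-values share the error term of 1 model, which raises the chance value: 20 simulations with no change in either comparison, with spreads drawn from the limma fit's prior and features selected in the same way, gave 10.1% on average, or 47.5 of 470, and at most 13.4%. The simulation drew features as independent with 1 common prior, while 1395 of the real features share all values with another. Its range may therefore be too narrow. Apart from the error term, the simulated comparisons were drawn independently, so mice or array effects common to both are not covered. On average 363 features were selected per simulation, fewer than the 470 listed. The simulation therefore does not decide whether 75 exceeds chance. The signal in arrays outside the main comparison is what drew attention to that comparison. The simulation and the tests of it were chosen after it was seen. Of the 23 genes named by the rule, 19 had the same direction there, 10 of them at an unadjusted p under 0.05 in the authors' model. In that deposited comparison Ddit4 had a log2 ratio of -1.43, Depp1 -1.19, Angptl4 -1.07, Trim63 -0.84, Map3k6 -0.83 and Cebpd -0.73. These 6 are among the 10. The other 4 genes had the opposite direction: Igkv4-56 (0.46, the one of them with an unadjusted p under 0.05), C1s2 (0.39), Cish (-0.097) and Olfr429 (-0.0030). Of the 32 unnamed listed features among the brightest, 27 had the same direction in both comparisons (exact 95% interval 67.2% to 94.7%). The red cell transcripts were lower in the arrays numbered 8, 10 and 12 too, with log2 ratios of -0.75 for Hbb-bt and -0.52 for Alas2, as was Gabarapl1 at -0.89. Over the whole list 312 of 470 features had the same direction in both comparisons (61.9% to 70.6%), and 87 of the 134 named ones (56.2% to 73%). Below the median level 188 of 310 listed features did (55% to 66.1%). These were 55 of 100 named ones (44.7% to 65%, which holds chance) and 133 of 210 unnamed ones (56.4% to 69.9%).

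If array measurement noise alone had made the differences of the 19 named listed features among the 10336 brightest, their direction in the other 6 arrays would match as often as not. It matched for 19 of 19, with an exact 95% interval from 82.4% upward, which argues against array measurement noise alone. The interval treats features as independent, but 15 of the 19 were lower and 4 higher in refed muscle, and they may have moved together. If the other arrays came from the same mice, chance differences between mice would recur in both comparisons, and the match does not speak to these. The order of the arrays stays open, because all 6 labelled arrays have numbers that place fasted before refed. The other arrays are compared in the same order of numbers. No label says that the numbers give the order in which arrays were processed. If they do, a step between early and late arrays and an effect of the meal on muscle may both give this pattern. These cannot be told apart here. A lower content of red cell RNA in both comparisons stays open as well for part of these genes, and was not tested in the arrays without labels.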

How the results depend on the processing

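The restriction to the 10336 brightest features, the red cell covariate and the adjustment of named members over a list alone were chosen after the data were seen. No feature passed limma at adjusted p under 0.05 in the main setting, after quantile normalization, median centring, either filter, array weights, a trend and robust prior, no moderation or without any 1 array, nor at adjusted p under 0.1 or for any of the authors' 470 entries. The 23 named genes kept their direction in all 324 values over 15 settings (Alas2 left out under the covariate it is part of), with a smallest adjusted p of 0.354. Most of these settings could not change a direction, so this is no test of its own. Filters and variance moderation leave a difference as it is. Leaving out or weighting arrays cannot reverse it where the groups do not overlap. Of the 324 values 3 moved by over 1.5 times, all with the red cell covariate: Gabarapl1 to -0.17, Angptl4 to -0.50 and Trim63 to -0.44. Under that covariate other differences grew by less than this, among them Pfkfb3 from -1.04 to -1.54, Chac1 from -0.82 to -1.13 and Myod1 from 0.64 to 0.83. Counts at unadjusted p under 0.05 moved with the number of features tested. Above the median level they were 385 higher and 585 lower (77 and 147 with 1.5-fold, 160 of the authors' entries). Among the 10336 brightest they were 180 and 238 (23 and 42, 51 entries). There 516.8 in both directions together were due by chance, so the brightest features held no excess. Above the 25th percentile 139 and 301 passed with 1.5-fold, and 279 entries. Without moderation these were 116, 202 and 259, and 0 glucocorticoid members passed over the list alone, as with the red cell covariate; other settings that kept all arrays gave 4 or 5.

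Leaving out 1 array at a time gave 663 to 1152 features higher and 973 to 1462 lower at unadjusted p under 0.05. With 1.5-fold these were 287 to 436 and 511 to 662, and the authors' entries 362 to 395. The main count of 247 higher with 1.5-fold became 436 without fasted replicate 5 and 386 without refed replicate 7. Between 2 glucocorticoid members (without refed replicate 9) and 5 (without fasted replicate 5) passed over the list alone. The cause was not tested. No paired analysis was possible because the groups share no replicate number. Averaging the features of a gene and the camera and fry set tests were not run, since other features carry no gene name; testing all features is the main setting.

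The 6 arrays allow 10 splits into 3 and 3, the real one included, too few for a share under 0.05. At the adjusted threshold all 10 gave 0 features. At unadjusted p under 0.05, 5 of the 10, the real one among them, gave at least the real 2009, the highest other being 2835. With 1.5-fold, 2 of the 10, the real one among them, reached the real 727, the highest other being 782.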

Other observations

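The look at single arrays and the red cell covariate were chosen after the data were seen, as were the genes of the next paragraph.

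Further entries of the authors' list went both ways. Ppbp, a platelet chemokine, was 1.597-fold lower, at 6.33 ± 0.20 against 7.01 ± 0.31 (log2 signal, SD, n = 3), and Ms4a4a, a membrane protein of immune cells, was 5.07 ± 0.21 against 5.85 ± 0.34. Of the T cell receptor segments, Trav6n-6 and Trbv10 were higher in refed muscle, at 3.76 ± 0.32 against 2.99 ± 0.38 and 3.71 ± 0.36 against 3.10 ± 0.23, and Trav16d-dv11 was 1.92-fold lower. The fixed macrophage, neutrophil and lymphocyte lists had 0 members in the authors' list. The bile acid and steroid sulphate transporter Slc10a6 was 5.53 ± 0.03 against 6.14 ± 0.42. Of 7 microRNA entries, Mir29a had the largest difference, at 3.72 ± 0.17 against 4.67 ± 0.33, and Mir148a and Mir130a were higher in refed muscle, at 2.20 ± 0.22 against 1.46 ± 0.11 and 3.24 ± 0.08 against 2.64 ± 0.18. None passed limma across all features. The 7 microRNA entries all lie below the median level of the array features.

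On refed replicate 7, 25 features lay more than 3 log2 units below the lowest of the other 5 arrays, with a median of 3.70 against 8.12. None has a symbol or is in the authors' list, and 24 of them are among the 413 features with the highest feature numbers. Refed replicate 9 had 2 such features, with 1 more above the other arrays, and the remaining arrays had 0. Without refed replicate 7, 3 of the glucocorticoid members passed over the list alone (Cebpd, Arrdc2 and Angptl4).

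A large part of the authors' list comes from one end of the feature numbers: 213 of its 470 entries, or 45.3%, are among the 4134 features with the lowest numbers, none with a gene symbol. In the limma fit these held 49.1% of the features with unadjusted p under 0.05 and at least 1.5-fold. The prediction that noisy features crowd there whatever the grouping was met: over the 9 other splits of the arrays the median share was 47.7% (39.4% to 52.5%). The median residual SD was 0.426 among them and 0.180 elsewhere. A candidate explanation is thus that this part of the list reflects the spread of these features rather than the meal; what the features measure is not given in the sources used here.

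Lower blood content of refed muscle might lower transcripts that blood cells carry, and the 6 glucocorticoid members were lower together with Alas2 and Hbb-bt. With the mean of these red cell transcripts per array as a covariate, the mean difference of the 6 members was -0.924 (SE 0.394, 95% interval -2.18 to 0.33) against -0.9995 (SE 0.223) without it, and the covariate's own coefficient was 0.093 (SE 0.372). By member, the limma intervals with the covariate, unadjusted for 6 genes, lay below 0 for Arrdc2 (-1.69 to -0.36), Cebpd (-1.70 to -0.25), Ddit4 (-2.71 to -0.063) and Gadd45g (-2.42 to -0.042). They held 0 for Trim63 (-1.02 to 0.15) and Angptl4 (-1.35 to 0.36). The 6 genes, like Alas2 and Hbb-bt, were known only through a list selected on these arrays. With the covariate 0 of the 6 passed over the list alone (smallest limma adjusted p 0.253). The intervals therefore do not decide whether red cell RNA is the whole cause for any member. The bound for the mean, 2 SE below 0, was set after the data were seen but before the covariate was fitted. It was passed, but it is narrower than the interval that 3 residual degrees of freedom give, which holds 0. For the 6 as a set, and for Trim63 and Angptl4 in particular, a fall that goes with the red cell transcripts cannot be told apart from the meal with 6 arrays. Whether red cells carry RNA of these genes was not examined. An effect of the meal stays open and untested.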
